A study of Mus musculus with 4 samples.

How the data were processed

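Total RNA from skin of C57BL/6 mice was labelled with biotin and hybridised to Affymetrix mouse gene arrays of the MoGene 1.0 ST design, per the labels and the file headers. On this array a transcript cluster is a set of probes spread along the exons of a gene, and its value averages over the transcript. There were 4 arrays in 2 groups of 2. The no K5-Cre group held replicate 1, labelled CflarF/+;Tnfrsf1a+/-, and replicate 3, labelled CflarF/F;Tnfrsf1a+/-. The K5-Cre group held replicates 2 and 6, both labelled CflarF/F;K5-Cre;Tnfrsf1a+/-. Neither no K5-Cre sample is labelled as carrying Cre, so both served as controls. The series text compares the CflarF/F genotypes only, and that comparison, without no K5-Cre replicate 1, was run as an alternative. The labels give no age, no sex, no body site and no batch, and do not say whether an array held RNA of 1 animal or of several. The p-values therefore measure only the spread between these samples, which may be technical.

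The deposited series table gives log2 values for 35557 transcript clusters per array. The array medians were 7.60 and 7.61 (no K5-Cre replicates 1 and 3) and 7.53 and 7.55 (K5-Cre replicates 2 and 6). In the same order, the 25th percentiles were 6.23, 6.26, 6.36 and 6.37, and the 75th percentiles 9.04, 9.02, 8.87 and 8.90. How the authors normalized these values is not given in the sources used here, and they were used as deposited. A second deposited table holds 1396 clusters with a linear signal per array, called raw by the authors, and a log2 value that is the log2 of that signal minus the mean of the 2 no K5-Cre arrays, with a largest gap of 1.64e-06. The same table holds the authors' ratio of each array against no K5-Cre replicate 1 as an absolute fold and as a log2 fold. Per the file headers, the authors kept clusters above the 20th percentile of the signal that differed at least 4-fold from no K5-Cre replicate 1 on at least 1 array, with annotation on mouse build mm9. How probes were summarised into clusters is not given in the sources used here. No per-sample column was left unused (0 columns).

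Clusters were named from the platform annotation, in which 21789 clusters have exactly 1 gene symbol, 1621 have several and 12147 have none. Of the first kind, 21698 had their symbol updated through the Entrez gene identifier in a RefSeq gene table. Clusters with several symbols or none were not used for genes. The design had called for detection calls. Such calls were not used here, and the fallback fixed beforehand was applied, in which a cluster entered if its mean log2 value over the 4 arrays lay above the median of all clusters, 7.61. For the same reason, the condition on named genes that a cluster be called present on both arrays of the higher group became a value above that level on both. For a gene with several clusters the one with the highest mean was used, which left 11255 genes. Since the mean was taken over both groups, a gene low in 1 group was tested only where the other group lifted it. The counts and medians of list members are therefore partly set by this filter. Of 613 genes with 2 or more clusters past the filter, 16 had clusters that passed the test in opposite directions.

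Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), 2 arrays against 2, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05 on the adjusted p. The moderated test had 5.01 degrees of freedom. An exact permutation test of 2 against 2 cannot give a two-sided p under 0.333, so every p rests on the variance model. Each error after a difference is the moderated standard error (SE), with n = 2 arrays per group. The number of arrays limits the precision, and the median SE was 0.12 on the log2 scale. As a description without a test, genes at least 2-fold apart whose groups did not overlap were counted.

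Before the data were examined, 33 gene lists were fixed, covering epidermal programmes, inflammation, cell death and the other cell types that a piece of skin can hold. They contain 917 genes, of which 833 had a named cluster and 629 were tested. The 30 lists with at least 5 tested members were tested with limma's camera, with a preset correlation between genes of 0.01 and adjustment over the 30 lists, and again with a correlation estimated from the 4 arrays. Counts of members past the threshold are given adjusted over all genes tested and adjusted over the list alone. A further 8 lists were written after the data had been seen: uterus, liver, imprinted growth genes, ribosomal proteins, oxidative phosphorylation, kallikreins and serpins, glycolysis, and Wnt, hedgehog and BMP signalling. Their results are in the closing section.

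The genes to be named were set by a rule before the data were examined. Cflar, Tnfrsf1a, Krt5 and the sex-linked genes were always included. The 12 genes with the largest rise and the 12 with the largest fall were added, among those past the threshold whose groups did not overlap and which lay above the filter level on both arrays of the higher group. In each list described, up to 4 members past the threshold with the largest change were added, or the 2 largest if fewer than 2 passed. Genes named outside this rule are marked as chosen after their values were seen.

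The test was tested on simulated data with the means and variances of these arrays and 200 of 11255 genes changed. It recovered 8% of genes changed 1.5-fold, 46% of those changed 2-fold, 84% of those changed 4-fold and 90% of those changed 8-fold, with 0 false calls. Far fewer genes changed there than passed in the data (63.97%), so these rates do not describe the test as applied to the data. A simulated shift of 0.5 in the cell cycle list was called by camera with the preset correlation and was not called with the estimated correlation, and 0 of the 29 other lists were called. Simulated genes were drawn independently, whereas the correlation estimated for the terminal differentiation list was 0.877. The simulation therefore does not tell how often camera calls a correlated list falsely. Alternatives fixed beforehand covered leaving out each array, quantile normalization, a shift of each array to the same median, no filter, a stricter filter (a mean above that of 75% of clusters), the mean over the clusters of a gene, each cluster tested on its own, other variance models, the estimated correlation and the authors' deposited fold-change table. Leaving out the genes of the X and Y chromosomes was added after seeing the data. Genomic positions are those of the authors' deposited table, on mm9. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.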

Results

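Gene expression was measured in the skin of mice heterozygous for Tnfrsf1a, which encodes the TNF receptor TNFR1. The mice carried floxed alleles of Cflar, which encodes cFLIP, an inhibitor of cell death triggered through death receptors. In the group labelled K5-Cre the Cre recombinase was driven by the keratin 5 promoter, which is active in basal keratinocytes. There were 4 arrays, 2 labelled K5-Cre (replicates 2 and 6) and 2 without K5-Cre (replicates 1 and 3), and 11255 genes were tested. The comparison asks which genes could stand in the way of epidermal differentiation and of keratinocyte proliferation. Across all clusters, which are not independent replicates, Pearson's r was 0.995 between the no K5-Cre arrays, 0.985 between the arrays labelled K5-Cre and 0.902 to 0.911 between arrays of different groups. The SD of the difference over tested genes was 0.12 within the no K5-Cre pair, 0.36 within the pair labelled K5-Cre and 1.13 to 1.16 across groups.

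All 3 clusters named Cflar, the targeted gene, were higher and not lower in the arrays labelled K5-Cre. The log2 signal of the cluster with the highest mean was 8.97 and 8.77 in the no K5-Cre arrays and 9.69 and 9.71 in the arrays labelled K5-Cre, a rise of 0.83 ± 0.12 (SE, n = 2 per group, adjusted p = 0.0029). The call was lost without no K5-Cre replicate 3 (adjusted p = 0.0545). The 2 other clusters named Cflar also rose, by 0.83 ± 0.10 and 0.46 ± 0.10 (adjusted p = 0.00163 and 0.0137, each cluster tested on its own). In the authors' deposited table, the 10 clusters numbered nearest to the first all lay on chromosome 3, and those nearest to the 2 others all lay on chromosome 1, where the gene is. Whether the first value is that of the gene itself or of a copy at another locus is therefore not settled. A cluster averages over the transcript, the labels do not give the floxed exon, and whole skin holds cells in which the keratin 5 promoter is not active. These values therefore do not check the labels, and each direction below rests on the labels. The name K5-Cre before an array or a replicate number stands for that label only. Tnfrsf1a, heterozygous in every sample, rose by 1.17 ± 0.11 (adjusted p = 0.000932). Krt5 rose by 0.30 ± 0.09 (adjusted p = 0.0342), a call that was lost without no K5-Cre replicate 1 (adjusted p = 0.204), without replicate 3 (adjusted p = 0.195) and without the variance trend (adjusted p = 0.062).

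The skin labelled K5-Cre differed from skin without K5-Cre in most of the genes tested. Genes of stressed keratinocytes, neutrophils and inflammatory signalling were higher, by a measured 115-fold at most, and genes of muscle, fat, connective tissue and mast cells were lower, by 65.7-fold at most. In all, 7200 of 11255 genes (63.97%) passed an adjusted p of 0.05, 2836 higher and 4364 lower, and 4055 did not pass. At least 2-fold differences with non-overlapping groups were found for 2891 genes, 1206 higher and 1685 lower. Past the threshold, 169 genes were at least 8-fold higher and 149 at least 8-fold lower. The groups did not overlap for 86.0% of the tested genes, where chance gives 33.3%. Against the CflarF/F control alone, the comparison the study states, 3831 genes passed, 1463 higher and 2368 lower, and 3946 passed without no K5-Cre replicate 3. The balance of directions depends on scaling: the median difference over all tested genes was −0.14 as deposited and 0.06 after each array was shifted to the same median, which gave 3866 higher and 3284 lower genes.

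S100a8, which encodes a subunit of the neutrophil and keratinocyte alarmin calprotectin, had the largest measured rise, from 5.69 ± 0.30 to 12.53 ± 0.12 (mean log2 signal ± SD, n = 2 per group), which is 115-fold. It lies on chromosome 3 from 90472993 to 90473956 (mm9). Cxcr2, a chemokine receptor of neutrophils (chromosome 1, 74200568 to 74207820), rose 88.0-fold, and Arg1, an arginase of activated macrophages (chromosome 10, 24635027 to 24647290), rose 87.3-fold. The kallikrein Klk6 rose 67.1-fold. Krt16, Krt6b and Krt6a, keratins that epidermis makes after injury, rose 57.8-fold, 53.8-fold and 52.6-fold. Krt6a and Krt6b are close relatives at overlapping positions on chromosome 15 (from 101520354 and from 101506454), so their signals may not be separate. The neutrophil collagenase Mmp8 rose 57.7-fold and the collagenase Mmp13 51.0-fold. The beta-defensins Defb14 and Defb4 rose 55.6-fold and 52.5-fold, and Ifitm6 rose 52.7-fold. The 12 genes had adjusted p values from 5.39e-05 to 7.26e-05. Of them, 11 had a no K5-Cre mean under the filter level of 7.61 and 7, S100a8, Cxcr2, Mmp8 and Defb14 among them, a mean under 6.23, the 25th percentile of all clusters in no K5-Cre replicate 1. Signal over background was not assessed, so the size and order of these folds are those of the deposited values.

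Car3, a carbonic anhydrase abundant in fat and muscle (chromosome 3, 14863509 to 14872532, mm9), had the largest measured fall, from 13.21 ± 0.01 to 7.17 ± 0.35 (mean log2 signal ± SD, n = 2 per group). Atp1b4 fell 62.2-fold. The sarcomere genes Neb, Myl1, Myh3, Ttn and Myh8 fell 49.0-fold, 46.4-fold, 39.3-fold, 38.5-fold and 37.4-fold. The 2 myosin heavy chain genes of developing muscle, Myh3 and Myh8, lie on chromosome 11 at 66893501 and 67090626. Mcpt4, a mast cell protease (chromosome 14, 56678580 to 56681147), fell 43.8-fold. Itm2a, Nrk and the angiotensin receptor gene Agtr2 fell 45.3-fold, 42.0-fold and 29.8-fold. The cluster named Mir377, a microRNA gene on chromosome 12, fell 43.4-fold with a larger spread between the arrays labelled K5-Cre (SD 1.07) than the other genes of this group. The adjusted p was between 5.39e-05 and 0.000739 for these 12 genes, whose means in the arrays labelled K5-Cre all lay under the filter level, so the same limit applies to their folds.

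**Figure D1:**
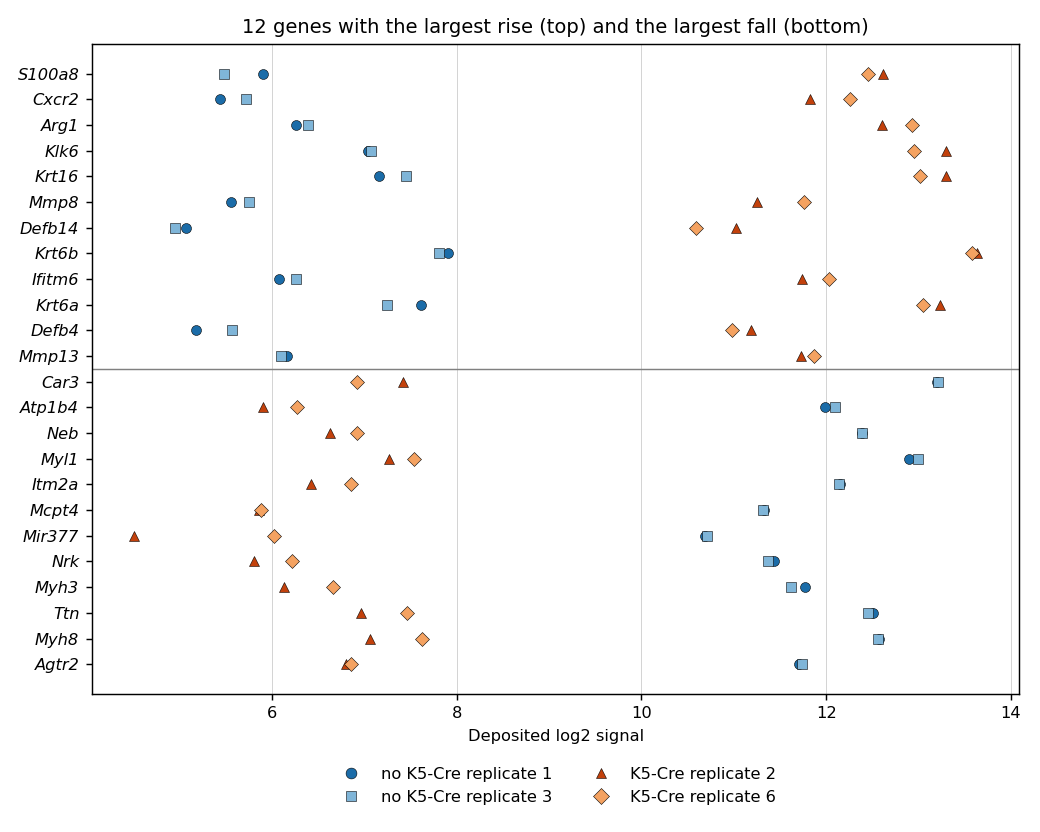
Deposited log2 signal (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 symbol per array. For S100a8 the means of the 2 groups lie at 5.69 and 12.53, and for Car3 at 13.21 and 7.17. The arrays of the 2 groups do not overlap for any of the 24 genes.

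Genes of the cornified layer were mostly higher in the skin labelled K5-Cre, where the lists of fibroblasts, skeletal muscle and adipocytes were lower (medians −2.70, −3.79 and −2.18). Of 45 tested genes of terminal differentiation, 36 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone. The median log2 difference was 1.27 (camera adjusted p = 9.34e-11, and adjusted p = 0.453 with an estimated correlation). All 48 genes of this list with a cluster were higher in K5-Cre replicate 2 than in replicate 6, with a median difference of 0.46. The largest rises were those of Rptn, encoding the cornified envelope protein repetin (48.4-fold), the late cornified envelope genes Lce3c (16.9-fold) and Lce3a (11.5-fold), and Spink5, encoding an inhibitor of epidermal proteases (6.22-fold). Chosen after their values were seen, the suprabasal keratins Krt1 and Krt10 and the envelope gene Lor differed by 0.04 ± 0.08, 0.01 ± 0.11 and −0.10 ± 0.13 and did not pass (adjusted p = 0.678, 0.927 and 0.517). Their signal lay near the top of the scale, with means of 13.73, 13.24 and 13.07 in the no K5-Cre arrays. Lor fell by 0.27 with K5-Cre replicate 2 left out, but rose by 0.06 without replicate 6 and by 0.09 with arrays shifted to the same median. Its direction thus depends on the array and the scaling used. Flg2, a filaggrin relative also chosen after its value was seen, fell by 1.24 ± 0.32 (adjusted p = 0.021), a call lost without either no K5-Cre array (adjusted p = 0.0752 without replicate 1 and 0.0675 without replicate 3).

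Genes of barrier lipid metabolism moved in the same direction. Of 28 tested, 21 rose, 2 fell and 5 did not pass, and 23 rose and 2 fell adjusted over the list alone (median 1.33, camera adjusted p = 2.36e-07, and adjusted p = 0.453 with an estimated correlation). Of the 32 genes with a cluster, 30 were higher in K5-Cre replicate 2 than in replicate 6 (median difference 0.52). Degs2, a sphingolipid hydroxylase gene, rose 23.4-fold and Dhrs9, a retinol dehydrogenase gene, 14.9-fold. Sdr9c7 and Nipal4, both needed for the lipid barrier of the skin, rose 5.09-fold and 5.05-fold. Among 31 regulators of epidermal differentiation, 16 rose, 5 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.40, camera adjusted p = 0.00208, and adjusted p = 0.502 with an estimated correlation). The epithelial transcription factor genes Ehf, Elf3, Hopx and Grhl3 rose 12.7-fold, 7.61-fold, 4.86-fold and 4.61-fold. Of 20 genes of cholesterol synthesis, 7 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone (median 0.35, camera adjusted p = 0.0163, and adjusted p = 0.604 with an estimated correlation). That shift was lost without K5-Cre replicate 2 (adjusted p = 0.16) and with no filter (adjusted p = 0.119). Msmo1 and Ebp, both of sterol synthesis, rose 2.54-fold and 2.01-fold.

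Basal keratinocyte genes went both ways. Of 26 tested, 10 rose, 8 fell and 8 did not pass, with the same counts adjusted over the list alone. The median was 0.13, the mean was −0.15, and the list did not pass (camera adjusted p = 0.447, and adjusted p = 0.78 with an estimated correlation). Krt15, a keratin of basal and hair follicle stem cells, fell by 2.84 ± 0.11, and Fras1, of the basement membrane, fell by 2.53 ± 0.11. Itga3, an integrin gene, rose by 1.85 ± 0.21, and the basal keratin Krt14, chosen after its value was seen, rose by 1.36 ± 0.08. Of 30 tested genes of keratinocyte stress and hyperproliferation, 29 rose, 0 fell and 1 did not pass, and 30 rose adjusted over the list alone. Their median of 4.15 was the second highest among the lists, after that of the 9 tested neutrophil genes (camera adjusted p = 2.1e-17, and adjusted p = 0.341 with an estimated correlation). The filter partly set this order. S100a8, Krt16, Defb14 and Krt6b led this list.

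Among simple and embryonic keratins, 4 of 6 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (median 1.57, camera adjusted p = 0.0469, and adjusted p = 0.453 with an estimated correlation). The shift was lost under quantile normalization (adjusted p = 0.0582) and with arrays shifted to the same median (adjusted p = 0.121). The simple keratin gene Krt18 rose 4.87-fold. Krt75 rose 5.22-fold and Krt79 fell 2.73-fold, and the name of the list does not describe either of them. Of 21 hair follicle genes, 7 rose, 12 fell and 2 did not pass, with the same counts adjusted over the list alone, and the list did not pass (median −0.67, camera adjusted p = 0.212, and adjusted p = 0.604 with an estimated correlation). The desmosome gene Dsc2 rose 16.6-fold, while the stem cell gene Lgr5 and the follicle transcription factor genes Lhx2 and Lef1 fell 8.49-fold, 6.44-fold and 5.38-fold.

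Genes of the cell cycle were lower as a group. Of 51 tested, 0 rose, 47 fell and 4 did not pass, with the same counts adjusted over the list alone, and the median was −1.38 (camera adjusted p = 9.34e-11, and adjusted p = 0.218 with an estimated correlation). Kif11, a motor of the mitotic spindle, fell by 2.46 ± 0.10. Ccna2, encoding cyclin A2, fell by 2.41 ± 0.10, the cytokinesis gene Kif23 by 2.38 ± 0.09 and the checkpoint kinase gene Bub1 by 2.35 ± 0.10. With arrays shifted to the same median, 44 fell and 1 rose, and the median was −1.18. The lists of fibroblasts, endothelium and muscle were lower in the same arrays (medians −2.70, −1.80 and −3.79).

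Most of the tested genes in each inflammatory list rose, in the arrays where the neutrophil and macrophage lists were also higher (medians 4.72 and 2.34). Of 40 cytokines and chemokines with a cluster, 21 were tested. Of these, 19 rose, 0 fell and 2 did not pass, with the same counts adjusted over the list alone (median 3.20, camera adjusted p = 6.31e-11, and adjusted p = 0.218 with an estimated correlation). The chemokine genes Ccl3 and Cxcl2 rose 48.1-fold and 45.6-fold, Ptgs2, encoding cyclooxygenase-2, 38.0-fold, and Tslp, an epithelial cytokine gene, 35.5-fold. Of 31 genes of the IL-6 and STAT3 response, 25 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone (median 1.14, camera adjusted p = 3.11e-08, and adjusted p = 0.218 with an estimated correlation). The acute-phase gene Saa3 rose 47.1-fold, Lcn2 37.3-fold, Lrg1 13.4-fold and the interleukin receptor gene Il4ra 11.9-fold. Of 18 genes of the NF-kappaB response, 16 rose and 2 fell, with the same counts adjusted over the list alone (median 0.93, camera adjusted p = 1.75e-06, and adjusted p = 0.218 with an estimated correlation). Bcl3, Nfkbiz and Tnfaip3, which act on NF-kappaB signalling, rose 6.71-fold, 4.20-fold and 3.72-fold. Of 23 interferon response genes, 19 rose and 4 did not pass, and 20 rose adjusted over the list alone (median 0.87, camera adjusted p = 6.4e-08, and adjusted p = 0.389 with an estimated correlation). The antiviral genes Oas2 and Rsad2 rose 5.29-fold and 5.12-fold.

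Most of the tested genes in each stress and repair list rose in the same arrays as the neutrophil and macrophage genes (medians 4.72 and 2.34). Of 20 immediate early and heat shock genes, 15 rose and 5 did not pass, with the same counts adjusted over the list alone (median 1.23, camera adjusted p = 1.72e-06, and adjusted p = 0.341 with an estimated correlation), led by Ier3 at 7.79-fold and Zfp36 at 7.38-fold. Of 30 genes of the wound edge and matrix remodelling, 21 rose, 6 fell and 3 did not pass, and 21 rose and 7 fell adjusted over the list alone (median 1.08, camera adjusted p = 9.19e-05, and adjusted p = 0.218 with an estimated correlation). Epgn, an EGF receptor ligand gene, rose 45.0-fold, and Mmp9 and Adam8, both encoding metalloproteases, rose by 4.70 and 4.67 on the log2 scale. Of 17 NRF2 and oxidative stress genes, 11 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone (median 0.63, camera adjusted p = 0.00208, and adjusted p = 0.246 with an estimated correlation). Gsta4 and Slc7a11, of glutathione metabolism, rose 24.95-fold and 11.3-fold.

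Genes of the cell death machinery went both ways. Of 28 tested, 15 rose, 6 fell and 7 did not pass, with the same counts adjusted over the list alone (median 0.47, camera adjusted p = 0.00215, and adjusted p = 0.453 with an estimated correlation). The gasdermin gene Gsdma rose 6.27-fold, the TNF receptor gene Tnfrsf1b 6.12-fold and Zbp1, which acts upstream of necroptosis, 3.85-fold, whereas Bcl2, which protects from apoptosis, fell 4.18-fold. Of 19 genes of the p53 response, 10 rose, 4 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.36, camera adjusted p = 0.00618, and adjusted p = 0.341 with an estimated correlation). Plk3 rose 5.09-fold and Ccng1 fell 4.02-fold. The shift of the cell death list was lost with the stricter filter (adjusted p = 0.0915), and that of the p53 list with the stricter filter (adjusted p = 0.0593) and with no filter (adjusted p = 0.103).

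Tested markers of neutrophils, of macrophages and monocytes and of Langerhans and dendritic cells were mostly higher. The 4 tested T cell and lymphoid genes went both ways, and mast cell genes fell. All 9 tested neutrophil genes rose, also adjusted over the list alone (median 4.72, camera adjusted p = 1.75e-07, and adjusted p = 0.246 with an estimated correlation), among them Retnlg at 47.8-fold and Ngp at 27.7-fold beside Cxcr2 and Mmp8. Of 24 genes of macrophages and monocytes, 23 rose and 1 fell, with the same counts adjusted over the list alone (median 2.34, camera adjusted p = 1.99e-10, and adjusted p = 0.38 with an estimated correlation). The integrin gene Itgam rose 27.0-fold and the receptor genes Clec4d and Cd14 20.02-fold and 18.3-fold. Of 9 genes of Langerhans and dendritic cells, 7 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone (median 0.89, camera adjusted p = 0.00825, and adjusted p = 0.38 with an estimated correlation). Cd74 and H2-Aa, of antigen presentation, rose 5.63-fold and 2.67-fold. Of 26 T cell and lymphoid genes with a cluster 4 were tested, too few for camera. The interleukin receptor gene Il7r rose 4.19-fold and Thy1, which fibroblasts also express, fell 2.08-fold, and in all 2 rose and 2 fell, also adjusted over the list alone. The calls of the others, a fall of Gata3 and a rise of Cd79b, were lost without either no K5-Cre array. Of 15 erythroid genes with a cluster 4 were tested. These 4 rose, also adjusted over the list alone, among them Slc4a1 at 7.27-fold and the heme synthesis gene Alas2 at 6.58-fold.

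Markers of the deeper skin and of mast cells were lower. Of 28 skeletal muscle genes, 27 fell and 1 did not pass, and 28 fell adjusted over the list alone (median −3.79, camera adjusted p = 9.34e-11, and adjusted p = 0.341 with an estimated correlation). Of 23 fibroblast genes, 22 fell and 1 did not pass, with the same counts adjusted over the list alone (median −2.70, camera adjusted p = 2.05e-08, and adjusted p = 0.242 with an estimated correlation). The matrix genes Ogn, Lum and Dpt fell 22.0-fold, 14.3-fold and 11.6-fold, and Dlk1 fell 18.6-fold. Of 13 adipocyte genes, 12 fell and 1 rose, with the same counts adjusted over the list alone (median −2.18, camera adjusted p = 0.00014, and adjusted p = 0.341 with an estimated correlation). Adipoq, encoding adiponectin, fell 18.8-fold and Retn, encoding resistin, 18.3-fold. Of 18 endothelial genes, 16 fell and 2 did not pass, with the same counts adjusted over the list alone (median −1.80, camera adjusted p = 1.68e-05, and adjusted p = 0.218 with an estimated correlation), among them Tek at 11.1-fold and Cdh5 at 10.03-fold. Of 15 mast cell genes with a cluster 9 were tested, and all 9 fell, also adjusted over the list alone (median −2.09, camera adjusted p = 0.000439, and adjusted p = 0.389 with an estimated correlation), with Mrgprb1 at 18.4-fold and Cpa3 at 17.7-fold after Mcpt4.

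The lists of sebaceous gland, melanocytes, Schwann cells and cartilage did not pass. Of 5 sebaceous gland genes 3 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone, with a median of 0.35 and a mean of −0.04 (camera adjusted p = 0.28). Scd1, a fatty acid desaturase gene, fell 11.6-fold and the lipid droplet gene Plin2 rose 4.59-fold. Of 9 melanocyte genes 1 rose and 3 fell, and 1 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.706), with a median of −0.08 that turned to 0.12 with arrays shifted to the same median. The receptor gene Kit, which mast cells also express, fell 3.62-fold and the pigment gene Dct 2.84-fold. Of 10 Schwann cell and nerve genes 1 rose and 6 fell, also adjusted over the list alone (median −0.61, camera adjusted p = 0.331). The myelin gene Pmp22 fell 5.37-fold. Of 5 cartilage genes 0 rose and 1 fell, also adjusted over the list alone (median 0.26, camera adjusted p = 0.28), and with arrays shifted to the same median 4 rose and 0 fell. In all, 18 of the 30 lists tested with camera shifted up, 6 shifted down and 6 did not pass. With a correlation estimated from the 4 arrays 0 lists passed (camera adjusted p from 0.218 to 0.78), and 6 had an unadjusted p under 0.05. The simulated shift was not called with this setting either, so a list that did not pass with it is not shown to be unshifted.

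**Figure D2:**
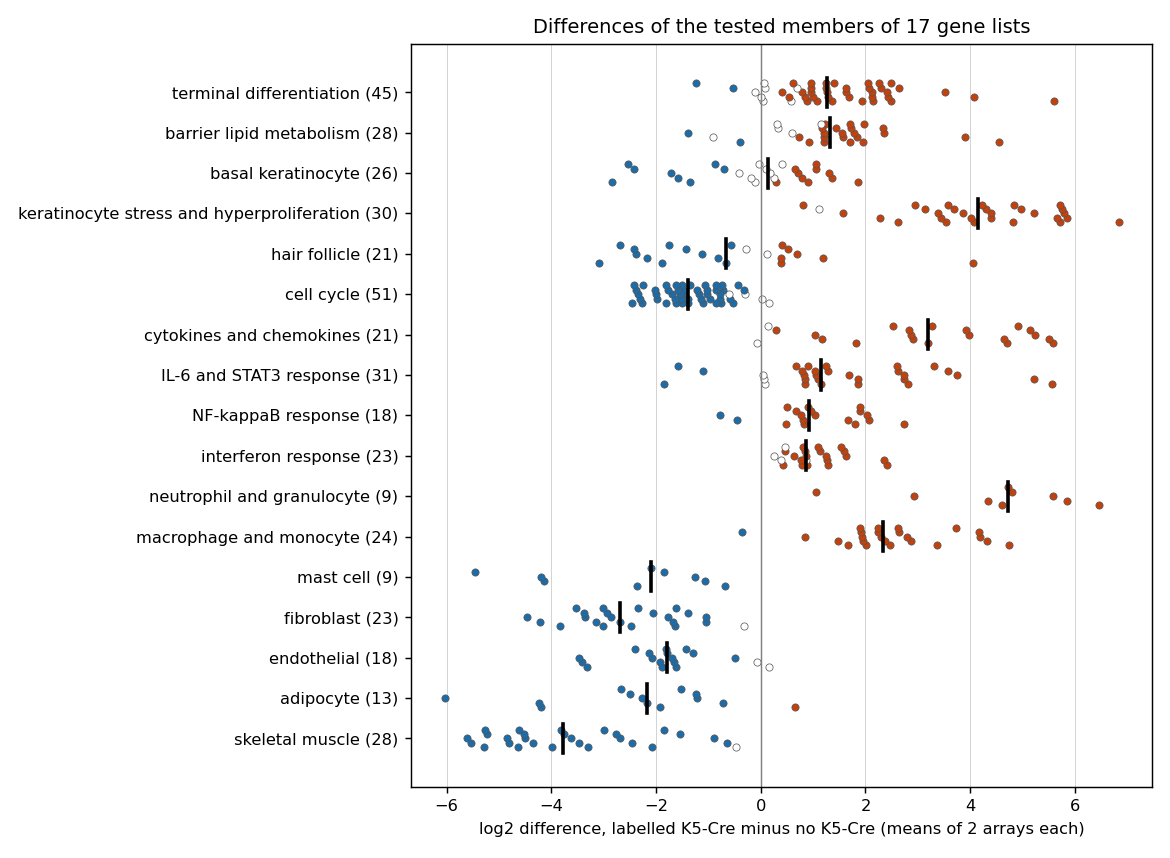
Log2 difference between the means of the arrays labelled K5-Cre and of those without K5-Cre (horizontal axis) for each tested member of 17 gene lists. Each point is a gene, filled where its adjusted p was under 0.05 (red higher, blue lower) and open where it was not, the thick bar is the median of the list, and the number of tested members stands in parentheses. The medians run from −3.79 for skeletal muscle to 4.72 for neutrophil genes.

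The sex-linked genes differed between the arrays, and K5-Cre replicate 2 stood apart. Xist, which is transcribed from the inactive X chromosome of females, had a log2 signal of 5.81 and 5.45 in no K5-Cre replicates 1 and 3, 8.83 in K5-Cre replicate 2 and 12.16 in K5-Cre replicate 6. The Y-linked genes had the reverse order across groups: Eif2s3y stood at 9.87, 10.15, 9.51 and 3.91, Uty at 9.19, 9.17, 8.31 and 4.88, and Kdm5d at 8.84, 8.45, 7.66 and 5.60 in the same arrays. By the test over groups Xist rose (adjusted p = 0.0128) and Kdm5d fell (adjusted p = 0.0466), while Uty and Eif2s3y did not pass (adjusted p = 0.0889 and 0.159). Adjusted over the list alone, 1 of these 4 rose and 0 fell. The call of Kdm5d was lost without either no K5-Cre array, with falls of 1.82 without replicate 1 and 2.21 without replicate 3. Uty fell by 4.30 without K5-Cre replicate 2 and by 0.87 without replicate 6, and Eif2s3y by 6.09 and 0.49. A lone array labelled K5-Cre gives no spread of its own, so no call is drawn from these last fits. Low Xist with high Y-linked signal, as in males, was seen in both no K5-Cre arrays, and the reverse, as in females, in K5-Cre replicate 6. K5-Cre replicate 2 had signals of both, with Y-linked values nearer to those of the no K5-Cre arrays than to those of replicate 6. Neither array labelled K5-Cre was like a male throughout, so sex cannot be told apart from the group here. Without genes of the X and Y chromosomes, an alternative added after seeing the data, 6979 genes changed, 2770 higher and 4209 lower. Leaving them out does not remove differences between the sexes in genes of other chromosomes. K5-Cre replicate 2 also had 10 genes at least 4-fold above every other array, against 1 for K5-Cre replicate 6 and 0 for each no K5-Cre array, over 19938 genes. They were chosen after their values were seen. Prap1 stood at 12.43 in K5-Cre replicate 2 and at 6.89 in replicate 6, Kap at 10.83 and 5.90, and the smooth muscle gene Actg2 at 11.19 and 7.67. Without K5-Cre replicate 2, 8947 genes passed, 3716 higher and 5231 lower.

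**Figure D3:**
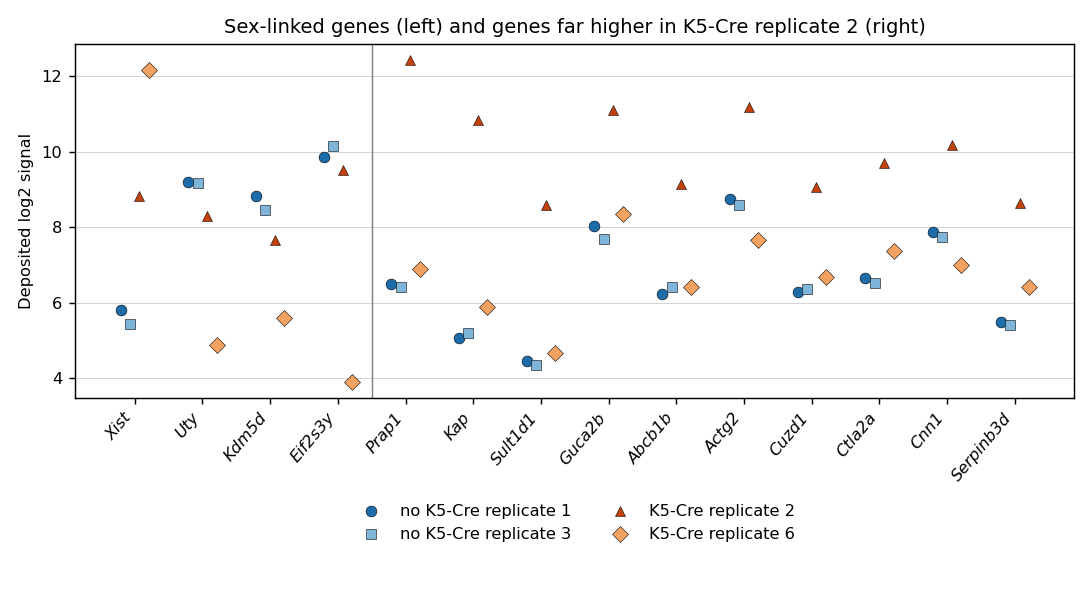
Deposited log2 signal (vertical axis) of the 4 sex-linked genes and of 10 genes at least 4-fold higher in K5-Cre replicate 2 than in each other array, with 1 symbol per array. Xist in K5-Cre replicate 2 lies at 8.83, between 5.81 and 12.16, while Prap1 lies at 12.43 there and at 6.89 in K5-Cre replicate 6.

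In the authors' deposited table of fold changes against no K5-Cre replicate 1, 540 clusters were at least 4-fold higher and 626 at least 4-fold lower in K5-Cre replicate 2. In K5-Cre replicate 6, 521 were higher and 626 lower by the authors' deposited table. Both arrays labelled K5-Cre shared 401 of the higher and 516 of the lower clusters in the authors' deposited table, and 0 clusters passed 4-fold in opposite directions. No K5-Cre replicate 3 differed at least 4-fold from replicate 1 in 1 cluster of the authors' deposited table, that of Alb, the serum albumin gene, chosen after its value was seen, which was 12.1-fold lower. The log2 folds of the authors' deposited table correlated with those of the series table at r = 0.998 for each K5-Cre array across its 1396 clusters, which are not independent replicates. All had the same sign (100%), and the slope was 0.919. Both tables describe the same arrays, and the authors kept these clusters for a 4-fold difference from no K5-Cre replicate 1. A high r and a shared sign were therefore likely from the start.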

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

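Signal outside the genes analysed also separated the groups. Of 5411 transcript clusters past the filter level that have no gene symbol or several, 39 were at least 4-fold higher in both arrays labelled K5-Cre than in both no K5-Cre arrays, and 40 were at least 4-fold lower. Of these, 16 and 14 have several gene symbols, and no gene is named from them.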

How the results depend on the processing

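Of the settings below, leaving out the genes of the X and Y chromosomes was chosen after seeing the data. The count of 7200 changed genes ranged from 3831 to 9147 when 1 array was left out (higher 1463 to 3716, lower 2368 to 5454). It was 3831 without no K5-Cre replicate 1 and 3946 without replicate 3, where the lone array is assumed to vary like the pair labelled K5-Cre (SD of the difference 0.36). It was 8947 without K5-Cre replicate 2 and 9147 without replicate 6, where the lone array is assumed to vary like the no K5-Cre pair (SD 0.12). With no filter, 11712 of 19938 genes passed, 6145 higher and 5567 lower, and the higher share of the changed genes was 52.47% against 39.39% with the filter (the cause was not tested). Over all clusters, the arrays labelled K5-Cre had the higher lower quartiles and the lower upper quartiles, and the filter kept clusters above the median. With the stricter filter, 3534 of 5484 passed, 1508 higher and 2026 lower, and 1429 were at least 2-fold apart with non-overlapping groups, where fewer genes were tested. Without genes of the X and Y chromosomes 6979 of 10941 passed. Quantile normalization gave 3393 higher and 3726 lower genes, of which 6539 were also among the 7200. Of the 7150 genes passing with arrays shifted to the same median, 6120 were. The count of 24 shifted lists was 19 with the stricter filter, which left 8 of the 30 lists, 3 of the 24 among them, with too few genes to test and ended the call of 2. It was 23 or 24 in the other settings with the preset correlation, and 0 with the estimated correlation. The 24 with no filter were not the same lists: 2 of the 24 lost their call there, and lists with too few genes past the filter were added. The simulated shift, in genes drawn independently, was lost with the estimated correlation too, so a lost call does not by itself show correlated genes. The estimated correlation was 0.877 for terminal differentiation and −0.0119 for the cell cycle. A correlation above the preset 0.01 therefore cannot be why the cell cycle list lost its call. The median shifts of terminal differentiation (1.27) and the cell cycle (−1.38) stayed with the estimated correlation, with camera adjusted p = 0.453 and 0.218 (the cause of the lost calls was otherwise not tested). In the other settings they ranged from 1.04 to 1.60 and from −1.41 to −1.16, past the threshold throughout. Of the 30 lists, 26 kept their side of the threshold in every setting that tested them but that of the correlation, 19 of them with a test in every setting, and the exceptions stand with their lists in the report. Of 159 named genes, 140 passed in every setting that tested them, 12 lost their call without 1 array, and 0 reversed a call. Of 1969 comparisons of named genes, 7 had another direction, in 4 genes that had not passed (Krt1, Krt10, Lor and Alb). Alb was called in opposite directions, 1.96 without no K5-Cre replicate 1 (adjusted p = 0.00875) and −1.95 without replicate 3 (adjusted p = 0.0113).

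No paired analysis was possible because the groups share no replicate number. Pseudocounts were not run, since the values are log2. The authors' deposited fold-change table gave no counts, since it holds only clusters chosen for a 4-fold difference. For named genes, its differences moved by more than 1 SD in 66 cases, with the same direction. Of the 3 splits of the 4 arrays into 2 and 2, only 1, the real one with 7200 genes, gave as many changed genes, and the highest other gave 0. With 3 splits a share under 0.05 cannot be reached. Each other split put 1 array of each label in either group, so the difference between the labels entered its spread. A low count there was therefore likely from the start, and the 0 decides nothing. Background levels were not used here, so the limit that signal over background sets was not assessed.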

Other observations

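The gene lists in this part were written, and the genes named in it chosen, after the data had been seen, and of the tests here only that of the uterine list against random lists was set before its result. Of 20 imprinted growth genes, 0 rose, 19 fell and 1 did not pass, with a median of −3.01, and 1 rose and 18 fell with arrays shifted to the same median. Mest, Ndn and Igf2, which encodes a fetal growth factor, fell, with log2 differences of −4.21 ± 0.10, −4.09 ± 0.11 and −2.003 ± 0.14 (limma, SE, n = 2 per group). The list was prompted by Dlk1, Mir377 and Zim1 among the falls, so its direction is not independent of them, and 2 of its tested genes, Dlk1 among them, are also in the fibroblast list. The fibroblast and skeletal muscle lists fell in the same arrays (medians −2.70 and −3.79). Of 28 genes of Wnt, hedgehog and BMP signalling, 2 rose, 19 fell and 7 did not pass (median −1.21). Sfrp2, a secreted Wnt modulator, the hedgehog receptor gene Ptch1 and Bmp4 fell, with log2 differences of −4.70 ± 0.10, −3.28 ± 0.17 and −3.005 ± 0.11. Of 19 kallikreins and serpins, 15 rose and 2 fell (median 2.14), with Klk9 up by 4.05 ± 0.12 after Klk6.

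Among genes of energy metabolism, of 13 glycolysis genes 8 rose, 2 fell and 3 did not pass (median 0.88). The glucose transporter gene Slc2a1 rose by 1.81 ± 0.09 and the hexokinase gene Hk2 by 1.503 ± 0.24, while Pfkm, the muscle phosphofructokinase gene, fell by 2.77 ± 0.11. Of 37 genes of oxidative phosphorylation 3 rose, 26 fell and 8 did not pass (median −0.54), and 20 fell with arrays shifted to the same median. The skeletal muscle and adipocyte lists were lower in the same arrays (medians −3.79 and −2.18), and glycolysis and oxidative phosphorylation were not tested against each other. Of 36 ribosomal protein genes 0 rose and 20 fell (median −0.29), and 7 fell with arrays shifted to the same median. Between the no K5-Cre arrays, Alb stood at 10.53 in replicate 1 and 6.61 in replicate 3, with 8.95 and 8.20 in K5-Cre replicates 2 and 6. The median difference of 10 liver genes between no K5-Cre replicates 1 and 3 was 0.76, and of the 3 that were tested 1 rose.

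In K5-Cre replicate 2, 10 genes outside the sex-linked list were at least 4-fold above every other array. Several of them, such as Prap1 and Cuzd1, are known from the uterus, and a list of 23 further uterine genes had not been looked at before it was tested. Its median difference between K5-Cre replicates 2 and 6 was 0.29, with 18 of 23 genes higher, above 100% of 10000 random lists matched on mean level (95th percentile 0.095), and against the mean of the no K5-Cre arrays it was 0.46, above 99.7% of them. A gap of this size was not particular to uterine genes: 6 of the 32 lists fixed beforehand, sex-linked genes aside, had a median difference at least as high, with 0.46 for terminal differentiation and 0.52 for barrier lipid metabolism. Only 5 of the 23 genes lay above the filter level, 1 is also in a list fixed beforehand, and Car12 stood at 10.14 against 9.66 in replicate 6, so RNA of uterine tissue stays open. A pool of male and female skin like that of the other arrays would not lie above all of them. The 10 genes lay 2.24 to 5.53 above the next array on the log2 scale, where the SD of the difference between replicates 2 and 6 was 0.36. This argues against such a pool as their source. They were picked for that excess, however, and K5-Cre replicate 6 was the only female-like array, so a pool with a female unlike it stays open. For the sex-linked signals a pool stays open, as all 4 genes lay between replicate 6 and the no K5-Cre arrays.

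Genes of fibroblasts, muscle, fat and endothelium were lower while those of terminal differentiation were higher. A larger share of epidermis in the pieces labelled K5-Cre could raise basal and terminal genes alike. The terminal differentiation median lay 1.14 above the basal one (0.93 to 1.31 over the 4 pairs of arrays), but basal genes went both ways with an SD of 1.27 over genes, so this gap decides nothing. The 20 fibroblast genes still above the filter level differed with an SD 8.57 times their median SE, which decides nothing about a smaller share of fibroblasts either, since other cells also express such genes and the fall itself set which genes stayed. A changed share of cell types, the age, body site and depth of the pieces, which the labels do not give, and the loss of Cflar in keratinocytes itself all stay open. Sex stays open too, since Xist stood at 5.81 and 5.45 in the no K5-Cre arrays and at 8.83 and 12.16 in the arrays labelled K5-Cre. The Y-linked genes of K5-Cre replicate 2 lay nearer to the no K5-Cre arrays, with Eif2s3y at 9.51 against 9.87 and 10.15, and 3.91 in replicate 6. Yet the lower lists differed little between replicates 2 and 6 (median difference −0.13 for fibroblasts, −0.09 for muscle, 0.28 for adipocytes, 0.11 for endothelium). Replicate 2 is 1 array with signals of both sexes, so this does not settle the part of sex.

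Clusters named Cflar were higher in the arrays labelled K5-Cre, where a loss in keratinocytes was designed. A near-identical copy measured by only 1 cluster may account for the cluster numbered among those of chromosome 3, but is argued against as the whole cause by the 2 other clusters, which also rose. Cflar transcripts of other cells could outweigh a loss in keratinocytes, and the median difference of 2.65 over macrophage and neutrophil genes shows that such cells' genes rose, but without sorted cells it decides nothing. The labels of the 2 groups exchanged cannot be told apart from this either: 3 clusters named Cflar rose, and the place of the deleted part is not given.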
